A study of Mus musculus with 2 samples.

How the data were processed

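RNA was measured in 2 pools of 50 Purkinje cells, each a laser-captured pool per the labels' protocol links, by RNA-seq with ERCC spike-ins. The labels link a Smart-seq protocol for pool 2, and that of pool 1 is not given in the sources used here, so a difference in library preparation cannot be ruled out. Per the labels, RNA over 200 nt was sequenced. Replicate numbers 1 and 2 were taken from the labels. Both pools carry the same donor identifier with different biosamples, so the labels do not say whether they came from separate animals.

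The authors quantified genes and transcripts from transcriptome alignments to mm10 with GENCODE release M4, per the file headers and accompanying notes. The aligner, the quantification tool, their versions and the strand setting were not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript, some of them fractional, and are not normalized. The deposited TPM values are scaled by the authors to the same total in each library, with the spike-ins included, so the share of spike-ins lowers every other TPM in that library. The deposited percent of each transcript in its gene was used for isoforms. Reads that map to several genes were divided by the authors' estimation, so paralogs, pseudogenes and overlapping genes have less certain values. Examples are Gm37376, which overlaps Malat1 on the opposite strand, and pseudogene copies of mitochondrial genes on chromosome 1. Confidence bounds deposited with the values were not used here.

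The files held 69691 entries: 43346 mouse genes, 97 spike-in entries and 26248 entries with numeric identifiers whose identity is not stated, and the last kind was left out of all gene lists and totals of genes. Symbols, gene types and coordinates came from GENCODE release M21 on the same assembly, which named 42462 of the genes and left 884 unnamed. Detection was a TPM of at least 1 in both pools. Log values are log2(TPM + 1), a scale that understates ratios of low genes. Levels of marker lists were compared as medians of log2(TPM + 1) within each pool. Families were described by the share of each member in the summed TPM. Correlations were taken over genes with a read in a pool.

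Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave the common dispersion with TMM scaling and filterByExpr, and DESeq2 1.42.0 size factors were an alternative scale. With 1 group, no test between conditions and no leave-out test was possible, and leaving out a pool leaves a single value. The median log2 ratio of a gene list between the pools was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression over 14933 genes. The percentile describes these libraries and is not a p-value. It was computed for 41 lists, those with at least 3 genes at a mean TPM of 0.500 or more. Counting intervals are exact Poisson at 95%, the Wilson interval is at 95%, and the limit for no counts uses 3 counts. All of these cover counting error only, since reads without molecular identifiers are not independent molecules. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

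The methods were tested on simulated data. With a simulated coefficient of variation of 0.2 over 15169 genes, 200 of them changed, edgeR returned 0.231, and with 0.4 over 14911 genes it returned 0.405. Random lists of 15 genes without a shift passed percentile 97.5 in 3 of 100 cases, and lists shifted by 0.5 passed in 100 of 100. The simulated genes varied independently, with the same spread at every level of expression. How often lists of related genes, or shorter lists, would pass without a shift was therefore not tested.

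The lists of 14 cell types, 13 functional groups and 25 families, the tests, most alternative settings and the rule for named genes were chosen before the data were examined. Named genes are the 4 members of each list or family with the highest mean TPM, members of the Purkinje cell list under the threshold or of the forebrain and outside-brain lists over it, the 12 nuclear protein-coding genes with the highest mean TPM, the 5 genes with the largest log2 ratio in each direction, and for isoforms 6 multi-transcript genes with the highest TPM. Where a list is summarised, some of its 4 are left out for length, and results of some genes and families are not reported here. Several settings were chosen after the data were seen: the adjustment of ratios for transcript length and expression by lowess with a span of 30%, the spike-ins as a scale, the minimum mean TPM of 0.500 for list ratios, and the tolerances of 0.01 for correlations and 10% for spreads when alternatives were compared. Alternatives tried were other thresholds, pseudocounts, scalings and filters, means in place of medians, count shares in place of TPM shares, and each pool alone.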

Results

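The data are gene and transcript expression profiles of Purkinje cells, the large GABAergic output neurons of the cerebellar cortex, from adult male wild-type C57Bl6 mice aged 8 months. The labels give 1 group with 2 biological replicates, called pool 1 and pool 2 here, and each library was made from a pool of 50 cells. The labels attach the same donor identifier to both pools, so they do not establish separate animals, and the spread between the pools may be technical. Pool 1 held 23830685 expected counts and pool 2 held 27907662. ERCC spike-in RNAs, synthetic transcripts added to each library, took 1.40% of the counts in pool 1 and 0.940% in pool 2. With 1 group there was no contrast between conditions, and no p-value for a condition could be given. The values below describe the 2 captured pools and the difference between them. Markers of glia, blood and other cells were detected too, so levels are not those of Purkinje cells alone. Values are the mean of the pools ± SD (n = 2) in TPM, the deposited length-corrected share of transcripts, unless stated otherwise, and coordinates are gene spans on mouse build GRCm38 (mm10).

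The most abundant nuclear protein-coding transcripts of the pools were those of Purkinje cell signalling and calcium-binding proteins. Pcp4, a calmodulin-binding peptide (chromosome 16, 96467606 to 96525793), led with 16961 ± 290.3 TPM, and Gng13, a G protein gamma subunit (chromosome 17, 25717171 to 25719406), followed with 9716 ± 206 TPM. The calcium binders Calm2 and Pvalb reached 7659 ± 1253 and 7401 ± 1092 TPM, and Pcp2, a Purkinje cell protein that acts on G protein signalling (chromosome 8, 3623371 to 3625545), reached 6384 ± 198 TPM. Other members of the top 12 were Dbi (5170 ± 609.9), Mt1 (4894 ± 116), Ckb (4756 ± 754), Itm2b (4209 ± 318), Ppia (4153 ± 365) and Aldoc (4135 ± 2441). The SD of Aldoc, a glycolytic enzyme, exceeded that of every other gene among these 12. Calm2 has close copies with which reads could be shared, so its level is less certain.

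Protein-coding genes took 75.04% of the TPM in pool 1 and 75.6% in pool 2, and genes on the mitochondrial chromosome took 6.37% and 6.64%. Nuclear pseudogene copies of mitochondrial genes, with which reads could be shared, are not in that share, so it may be too low. At a TPM of at least 1, 12495 genes were detected in both pools, 11092 of them protein-coding, while 711 passed in pool 1 alone and 652 in pool 2 alone. At a TPM of at least 5 the count in both pools was 8223. Genes seen in 1 pool alone were low, with a median of their mean TPM of 1.01. Of the genes at a TPM of at least 10 in pool 1, 99.9% were detected in pool 2.

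Purkinje cell markers were high in both pools, and all 15 genes of the list fixed for this cell type were detected. After Pcp4, Gng13 and Pcp2, the highest was Car8, which binds the IP3 receptor (2925 ± 728 TPM; chromosome 4, 8143362 to 8239041). Skor2, a transcriptional corepressor, was the lowest, with TPM values of 1.28 in pool 1 (95% counting interval 1.01 to 1.60 from 77 expected counts) and 1.11 in pool 2 (0.887 to 1.37 from 85). The median of the list was 457 ± 127 TPM.

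**Figure D1:**
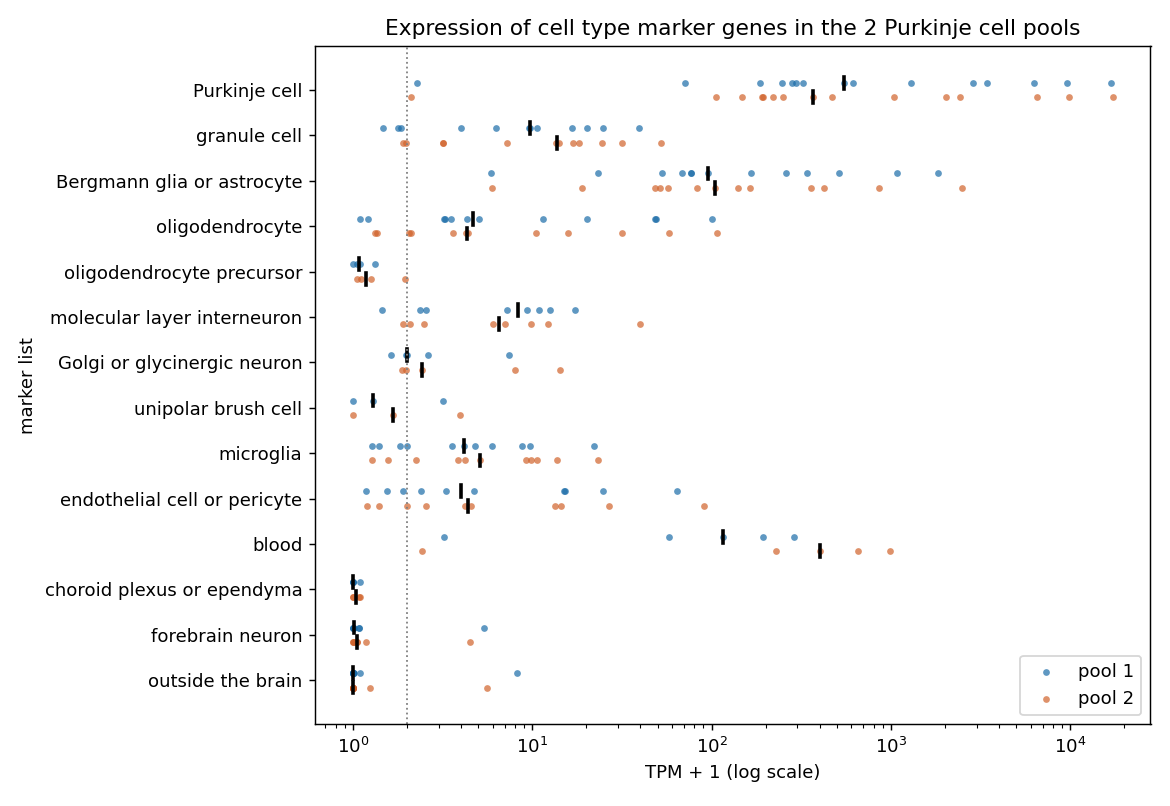
TPM + 1 on a log axis (x) for the members of each marker list (y) in pool 1 and pool 2, 1 point per gene, with black bars for the list medians and a dotted line at a TPM of 1. The Purkinje cell list has a median of 547 TPM in pool 1 and 367 TPM in pool 2, and the lists for forebrain neurons and for tissues outside the brain lie near 0 except for Neurod6 and Myl2.

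Markers of most other cerebellar cell types lay far below the Purkinje cell list. No reference level of each list in its own cell type was used. The differences therefore do not give the share of RNA from each cell type. The granule cell list was lower by 5.28 ± 0.77 on the log2 scale, with 9 of 12 genes detected and Gabra6, the GABA-A receptor subunit of granule cells, highest at 44.8 ± 9.01 TPM, followed by Neurod1 (27.1 ± 4.96), Etv1 (21.2 ± 2.99) and Zic1 (16.4 ± 1.17). The oligodendrocyte list, with the myelin genes Cnp (103 ± 5.54 TPM), Mbp (52.1 ± 6.96) and Mobp (17.0 ± 3.19), was lower by 6.65 ± 0.33, and 10 of its 12 genes were detected. Molecular layer interneuron markers were lower by 5.94 ± 0.16 with 7 of 8 detected. By the mean of the pools they were led by Prkcd (24.2 ± 20.4 TPM), Nxph1 (13.8 ± 3.68), Kit (8.82 ± 3.93) and Tfap2b (8.63 ± 0.368). Prkcd had 9.83 TPM in pool 1, below Nxph1, and 38.65 in pool 2. Microglial markers were lower by 6.61 ± 0.62 with 8 of 11 detected, among them the complement gene C1qb (10.7 ± 2.91 TPM). Endothelial and pericyte markers were lower by 6.75 ± 0.52 with 7 of 10 detected, led by Ly6c1 (76.3 ± 19.2 TPM) and Vtn (24.7 ± 1.22). Golgi or glycinergic neuron markers were lower by 7.67 ± 0.60 with 3 of 5 detected, and unipolar brush cell markers by 8.25 ± 0.68 with Calb2 alone of 3 detected (2.56 ± 0.566 TPM). None of the 4 oligodendrocyte precursor genes (lower by 8.64 ± 0.50) and none of the 4 choroid plexus or ependyma genes (lower by 8.78 ± 0.45) passed a TPM of 1 in both pools.

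The marker list of Bergmann glia and astrocytes stood closest among the solid-tissue lists, lower than the Purkinje cell list by 2.17 ± 0.49 on the log2 scale, and all 13 of its genes were detected. Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188), reached 2158 ± 472 TPM, Slc1a3, the glial glutamate transporter (chromosome 15, 8634124 to 8710764), 968 ± 164 TPM, Fabp7 469 ± 64.0 TPM and S100b 347 ± 13.6 TPM. Blood markers were also high and differed between the pools, with all 5 detected: Hba-a2 had 285 TPM in pool 1 and 991 in pool 2, and Hbb-bs had 193 and 655. The Purkinje cell list exceeded the blood list by 1.06 ± 1.68, a difference within the spread of the pools. It was 2.25 in pool 1 alone and turned to -0.12 in pool 2 alone. With CPM values, which are not corrected for transcript length, that difference was 4.29. Of 7 forebrain neuron genes only Neurod6 was detected (4.37 and 3.50 TPM), and of 10 genes of tissues outside the brain only Myl2 (7.2 and 4.58 TPM), and these lists were lower by 8.77 ± 0.45 and 8.81 ± 0.41.

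Genes of metabotropic glutamate and calcium store signalling, the pathway that parallel fibres engage in these neurons, were expressed throughout: all 18 were detected, with a list median of 127 ± 23.4 TPM. Besides Car8, the highest were the IP3 receptor Itpr1 (457 ± 127 TPM; chromosome 6, 108213096 to 108551109) and the calcium pump Atp2a2 (429 ± 99.4). All 8 genes of the calcium-binding list were detected, with a median of 4568 ± 249 TPM. All 16 genes of intrinsic excitability were detected, with a median of 23.9 ± 2.84 TPM, led by the calcium-activated potassium channel Kcnma1 (170 ± 47.5), Scn2b (96.2 ± 23.4) and Scn1a (82.0 ± 29.8). The 5 genes of GABA synthesis, packaging and uptake were all detected, with the synthetic enzyme Gad1 (385 ± 56.0 TPM) above Abat (81.6 ± 22.3) and Gad2 (70.0 ± 25.9).

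Among 11 transcription factors of Purkinje cells, all were detected, led by Rora (317 ± 51.9 TPM), Lhx1 (73.4 ± 12.8), Ebf1 (46.6 ± 12.6) and Bcl11a (45.0 ± 2.77). Of 26 genes of inherited ataxia, 23 were detected in both pools, among them Itpr1 and Atxn10 (136 ± 14.7 TPM), while Pdyn had no counts and Tgm6 had 0 and 3 counts. Pdyn and Tgm6 lie outside the naming rule and were named after their values were seen. All 15 nuclear genes of oxidative phosphorylation were detected with a median of 537 ± 14.8 TPM, led by Ndufa4 (4000 ± 394) and Cox6c (2956 ± 517). All 8 neurofilament and axon genes were detected with a median of 87.1 ± 8.35 TPM, led by Stmn3 (2037 ± 128) and Stmn2 (457 ± 2.56). Immediate early genes were low, with 5 of 10 detected and none of the 4 highest above Dusp1 at 4.16 ± 0.219 TPM (Fos, 2.88 ± 1.22). Of the heat shock and stress genes, 5 of 8 were detected, with Hsp90aa1 (2098 ± 231 TPM) and Hspa8 (1911 ± 98.7) highest. The Y-linked genes Eif2s3y (77.2 ± 7.23 TPM), Ddx3y (35.5 ± 3.54), Uty (16.9 ± 2.99) and Kdm5d (9.96 ± 2.58) were detected and Xist was listed at a TPM of 0 in both pools, which goes with the male label.

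In 14 of the 17 receptor, channel and signalling families reported here the leading member took over 50% of the summed TPM of its family. By expected counts the member that led by TPM took over 50% in 13. The other 8 of the 25 families fixed in advance are not reported, so this tally need not hold for all 25. Itpr1 took 98.9% ± 0.0116 of the IP3 receptors, Kcnn2 96.8% ± 0.232 of the SK channels and Homer3 95.8% ± 0.615 of the Homer scaffolds. Atp2a2 held 93.9% of the SERCA pumps, the GABA transporter Slc32a1 92.0% of the vesicular transporters, Atp2b2 87.6% of the plasma membrane calcium pumps, Plcb4 86.8% of the phospholipases C beta and Slc1a3 86.5% of the glutamate transporters. Grik1 held 73.7% of the kainate receptor subunits and Scn1a 70.9% of the sodium channel alpha subunits. Shares were 68.8% for Grin1 among NMDA receptor subunits, 65.3% for Scn2b among sodium channel beta subunits, 61.4% for Kcna1 among Kv1 channels and 59.7% for Cacna1a among calcium channel alpha-1 subunits. By expected counts, which weight long transcripts more, the share of Cacna1a was 36.1% and that of Cacna1g 53.1%. Among the vesicular transporters Slc17a6 had no counts in either pool, which allows TPM values of up to 0.0358 in pool 1 and 0.0282 in pool 2. Gabrb1 (47.3%) and Gabrb2 (40.2%) shared the GABA-A beta family, with an SD between the pools of 11.6 for Gabrb1 that exceeded their difference, Gria2 held 43.2% ± 0.995 of the AMPA receptor subunits, and Syt4 (39.5% ± 0.957) and Syt2 (38.4% ± 5.25) led the synaptotagmins within their spread. The SD of these leading shares between the pools ran from 0.0116 for Itpr1 to 11.6 for Gabrb1. Slc1a3 is also a glial marker, so its family share includes any glial RNA in the pools. The other shares may also include RNA of glia and other cells, whose markers were detected. All shares therefore describe the pools and not Purkinje cells alone.

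**Figure D2:**
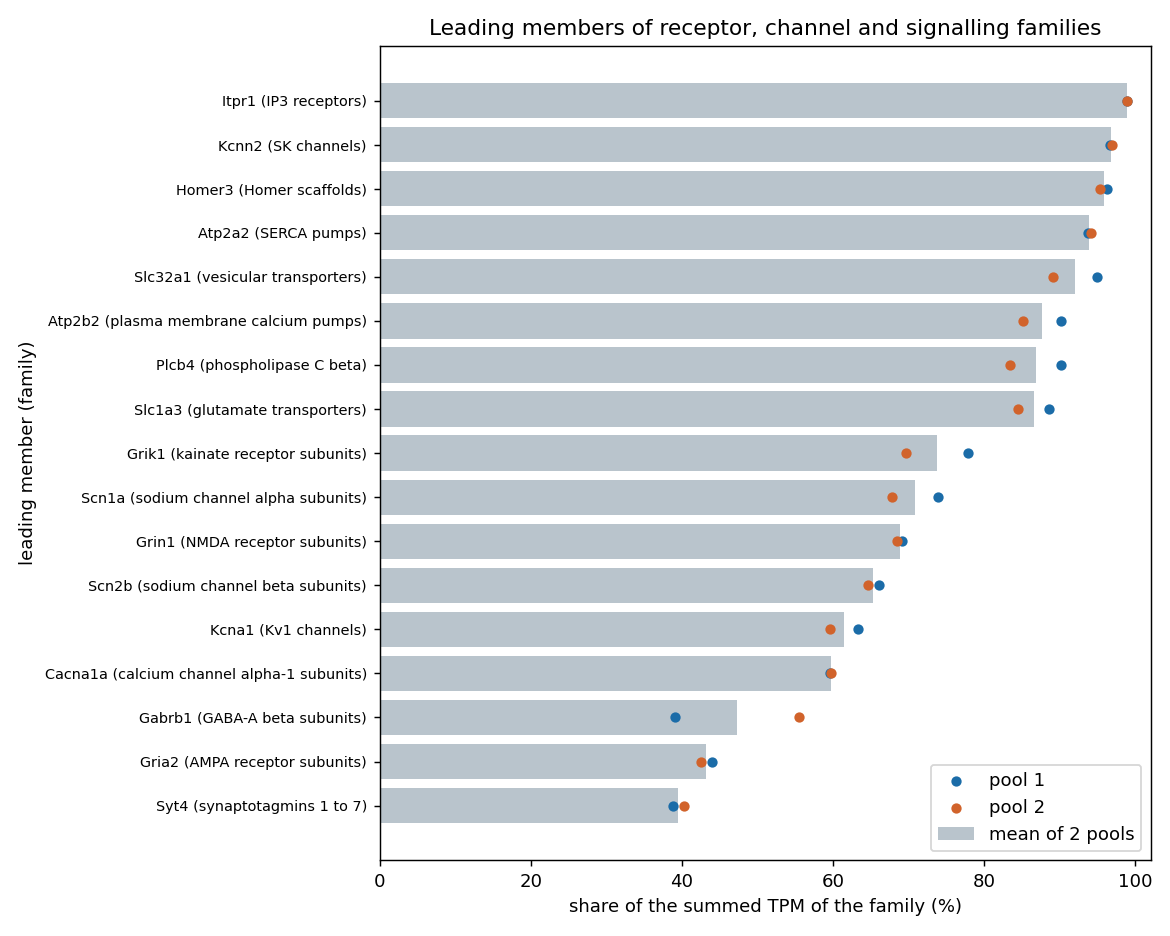
Share of the summed TPM of each of 17 families in percent (x) taken by its leading member (y), with grey bars for the mean of the 2 pools and points for pool 1 and pool 2. Shares run from 98.9% for Itpr1 to 39.5% for Syt4, and the points for Gabrb1 lie widely apart.

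The main transcript was mostly the same in both pools. Among 4584 genes with 2 or more transcripts and a TPM of at least 10, 4193 (91.5%, 95% Wilson interval 90.6 to 92.2) had the same leading transcript. For Gng13 the leading transcript took 89.6% ± 0.665 of the gene, for Calb1 95.6% ± 0.0990, for Dner 99.5% ± 0.0566 and for Atp2a2 75.8% ± 1.41. Pcp2 was split, with 36.3% ± 2.19, 31.0% ± 2.59 and 30.02% ± 5.00 for its 3 leading transcripts.

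The pools resembled each other closely at the level of single genes. Over 22727 genes with a read, Pearson's r of log2(TPM + 1) was 0.986 and Spearman's rho was 0.943, both across genes, which are not independent replicates. The SD of the log2 ratio between the pools was 0.53 at a mean TPM of 1 to 10, 0.35 at 10 to 100 and 0.28 at 100 or more. The biological coefficient of variation, the common dispersion from edgeR on its square-root scale, was 19.2% over 14863 genes. A chi-square test of the counts gave 40.0 per degree of freedom over 17207 degrees of freedom. It takes reads as independent, which amplified reads are not, so it shows only that the counts differ by more than sequencing 1 library again would give, and says nothing of the cells.

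Several gene groups differed between the pools. Log2 ratios here are of pool 2 over pool 1 on the log2(TPM + 1) scale and are relative to the total. The spike-ins had a median log2 ratio of -0.71, so taking them as the scale subtracts that negative value from every gene's ratio, which raises it, and turns each negative list median below positive. Of 41 lists with at least 3 genes in the comparison, 17 lay outside the central 95% of random lists matched on expression, and 12 of 22 did among the marker and functional lists. Most genes of Purkinje cells were lower in pool 2 relative to the total: the median log2 ratio was -0.33 for the Purkinje cell list (11 of 15 genes lower), -0.38 for metabotropic glutamate and calcium store signalling (16 of 18 lower) and -0.53 for intrinsic excitability (13 of 16 lower), each below all 10000 random lists. The 4 Purkinje cell genes higher in pool 2 were the 3 most abundant, Pcp4 (0.035), Gng13 (0.043) and Pcp2 (0.063), which turned to -0.082, -0.057 and -0.039 after adjustment, and Slc1a6 (0.57, adjusted 0.64), which is also in the zebrin-positive list. The ataxia list (-0.29, percentile 0.230, 21 of 26 lower), the GABA list (-0.46, percentile 0.565, 5 of 5 lower), the transcription factor list (-0.33, percentile 1.26, 8 of 11 lower) and the Bergmann glia and astrocyte list (-0.25, percentile 0.740, 9 of 13 lower) were also low. Granule cell genes were higher in pool 2 (0.36, percentile 99.97, 11 of 12 genes higher), as were microglial genes (0.29 over 9 genes, percentile 99.3, 9 of 11 higher) and blood genes (1.79, above all random lists, 4 of 5 higher). These lists overlap: Itpr1, for example, stands in the Purkinje, signalling and ataxia lists.

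Genes of the zebrin bands, the parasagittal stripes of Purkinje cells defined by aldolase C, went opposite ways between the pools. The zebrin-positive list was higher in pool 2 (0.57, percentile 99.9), with Aldoc at 2409 TPM in pool 1 and 5861 in pool 2, Slc1a6 at 69.9 and 104, and Plcb3 at 7.85 and 11.8. The zebrin-negative list was lower relative to the total (-0.53, percentile 0.975). Plcb4 had 352 and 177 TPM in pools 1 and 2, Nefh 88.9 and 66.2, and Ebf2 24.5 and 16.6. With the spike-ins as the scale the list median was 0.18, but Plcb4 fell by more than the spike-in median and stayed lower. Each list holds 3 genes.

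**Figure D3:**
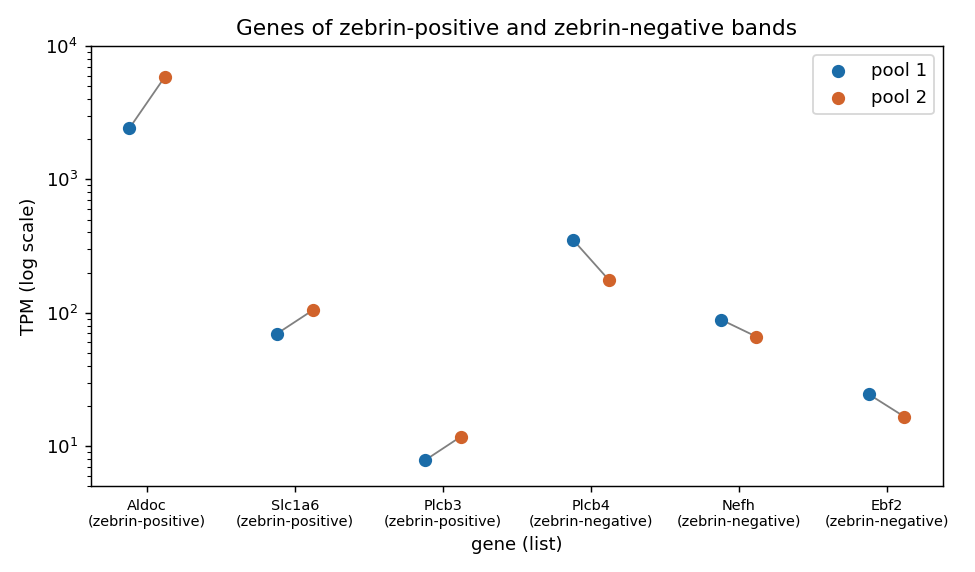
TPM on a log axis (y) of the 3 zebrin-positive and 3 zebrin-negative genes (x), with 1 point per pool joined by a grey line. Relative to the total, the zebrin-positive genes are higher in pool 2 (Aldoc, 2409 and 5861 TPM) and the zebrin-negative genes higher in pool 1 (Plcb4, 352 and 177 TPM), while with the spike-ins as the scale the zebrin-negative list median is 0.18.

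The pool ratio was also lower for longer transcripts. Among genes at a mean TPM of at least 10, the median log2 ratio was 0.17 for 205 genes with a mean transcript length under 500 nt, 0.12 for 500 to 1000 nt, 0.02 for 1000 to 2000 nt, -0.17 for 2000 to 4000 nt and -0.36 for 715 genes of 4000 nt or more. After adjustment for transcript length and expression, 12 of the 41 lists lay outside the central 95%. The lists of metabotropic glutamate and calcium store signalling (-0.21, percentile 0.07), intrinsic excitability (-0.28, percentile 0.03) and inherited ataxia (-0.18, percentile 0.3) stayed outside it. The Purkinje cell list (-0.22, percentile 0.09), granule cell list (0.47, percentile 99.99), microglial list (0.46, percentile 99.9), blood list (1.71, above all random lists) and zebrin-positive list (0.74, percentile 99.98) also did. The zebrin-negative (-0.28, percentile 3.97), Bergmann glia and astrocyte (-0.086, percentile 11.8), GABA (-0.23, percentile 4.02) and transcription factor lists (-0.11, percentile 15.2) did not. The oligodendrocyte list, inside it before (-0.23, percentile 10.2), lay outside it after adjustment (-0.24, percentile 1.71).

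**Figure D4:**
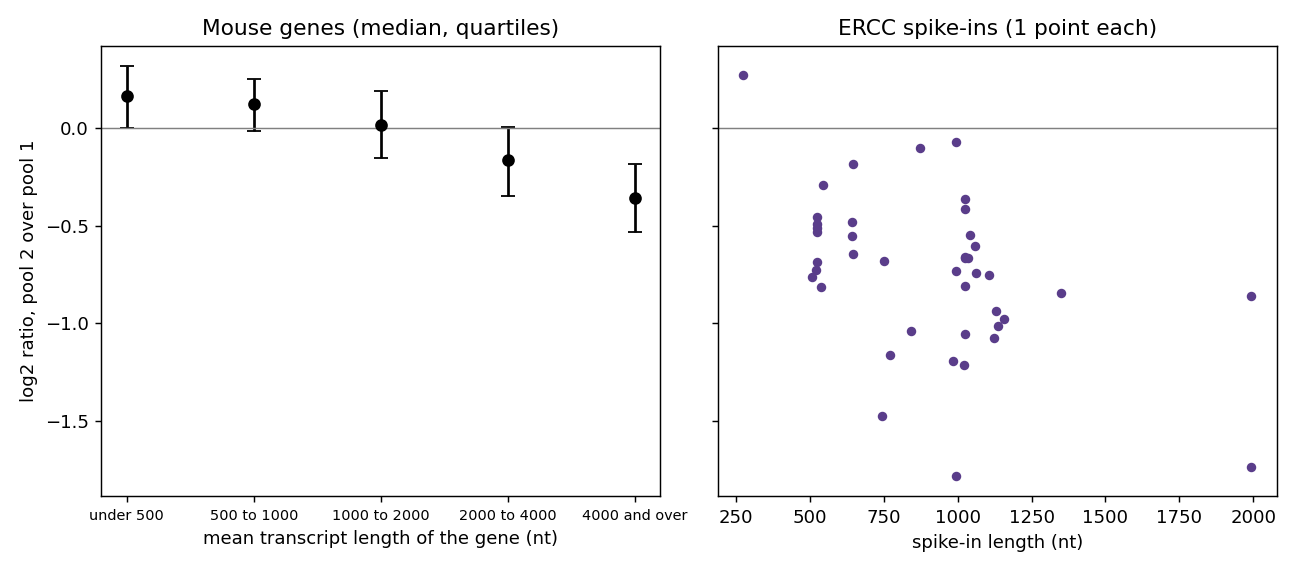
Log2 ratio of pool 2 over pool 1 (y) by transcript length in nt (x), as medians with quartiles for mouse genes at a mean TPM of at least 10 (left) and as 1 point per ERCC spike-in (right). Medians of mouse genes run from 0.17 under 500 nt to -0.36 at 4000 nt or more, and 41 of 42 spike-ins lie below 0.

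The remaining marker and functional lists with a percentile lay inside the central 95% by TPM ratio, with and without the adjustment. Their median log2 ratios were -0.10 for molecular layer interneurons, 0.10 for Golgi or glycinergic neurons, 0.08 for endothelial cells and pericytes, 0.06 for calcium binding, -0.09 for neurofilament and axon genes, 0.04 for oxidative phosphorylation, 0.11 for immediate early genes, 0.01 for heat shock and stress genes, and -0.27 for the sex check. With counts scaled by TMM or by DESeq2 size factors, for which no percentile was computed, the endothelial and pericyte median was 0.38 with both and that of oxidative phosphorylation 0.15 with both. On the same scales the microglial median was 0.54 and 0.53, that of Bergmann glia and astrocytes -0.096 and -0.099 and that of the transcription factors -0.12 and -0.13. After adjustment the signs turned for interneurons (0.066), neurofilament and axon genes (0.030) and calcium binding (-0.014). Among the families with a percentile, those of AMPA receptors (-0.65), GABA-A alpha (-0.59) and beta subunits (-0.58), Kv1 channels (-0.52) and sodium channel beta subunits (-0.50) lay low outside the central 95%, and all turn positive with the spike-ins as the scale. After adjustment the AMPA receptors (-0.40) and GABA-A alpha subunits (-0.37) stayed outside it, and the protein kinases C (0.35) came to lie above it.

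Single genes that differed most were few. The comparison covered 6423 genes with a mean TPM of at least 10 and a count of at least 100 in a pool. Of these, 59 differed by over 2-fold in TPM + 1, 16 higher in pool 2 and 43 higher in pool 1. TPM also depends on the estimated transcript length, and for some of the genes higher in pool 1 the expected counts differed by under 2-fold. Th, the tyrosine hydroxylase of catecholamine synthesis (chromosome 7, 142892752 to 142931128), had the largest ratio, at 1.63 TPM in pool 1 (56 counts) and 77.4 in pool 2 (3371 counts). Hbb-bt, Hba-a1 and Hba-a2, haemoglobin genes, were 3.98-fold, 3.51-fold and 3.48-fold higher in pool 2, and Prkcd, a protein kinase C, was 3.93-fold higher (9.83 and 38.6 TPM). Zfp965 (chromosome 2, 175469985 to 175482171) was higher in pool 1 at 57.0 against 3.16 TPM, as were Gm13502 (20.1 and 1.25), Zfp993 (18.2 and 3.53), Gm10801 (47.2 and 14.4) and Gm10800 (195 and 63.4). The haemoglobin genes and these zinc finger and predicted genes have close copies with which reads could be shared, so their separate values are uncertain. With n = 2 and no contrast, no gene was tested.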

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

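No tests were run in this part, and no biological explanation was tested. The entries with numeric identifiers, which no comparison used, held a summed expected count of 9.67 in pool 1 and 15.9 in pool 2. Each sum is above 3, the limit that a summed count of 0 would allow, but there are no control samples, and so few counts over so many entries do not show that any entry holds signal. Of these 26248 entries, 3 had a count in pool 1, 7 in pool 2 and 2 in both.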

How the results depend on the processing

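The length and expression adjustment and the spike-in scale were chosen only after the results were seen; the other alternatives were set beforehand. Among the alternative values, 177 stayed within the spread or tolerance, 86 moved beyond it and 9 turned the sign of a blood list difference or of a list outside the central 95%. For list differences and family shares, a pool alone always lies within the SD of the 2 pools. Such values count among the 177 by construction, unless the sign turned, and are no evidence of stability. Gene counts had a wide tolerance: 17168 at a TPM of at least 0.1 and 14914 at an expected count of at least 10 also stayed. In all, 16 values had the opposite sign, 12 with the spike-ins as the scale, 3 with the adjustment and 1 in pool 2 alone. No paired analysis was possible because the labels give 1 group. For the changes below the cause was not tested unless stated.

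A TPM of at least 5 left 8223 genes detected by construction, and the members detected became 5 (oligodendrocyte), 1 (Golgi or glycinergic neuron), 0 (unipolar brush cell), 3 (microglia), 4 (endothelial cell or pericyte), 0 (forebrain neuron), 0 (outside the brain). With a pseudocount of 0.1, Pearson's r was 0.963. Spearman's rho was 0.970 over genes with a mean TPM of at least 1 and 0.966 with CPM values. The biological coefficient of variation was 22.3% with no filter, and the share of genes with the same leading transcript was 87.5% at a TPM of at least 1 and 94.8% at a TPM of at least 50.

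The Purkinje cell list stayed above every other cell type list under each alternative except the blood list, where each pool alone gave -0.12 to 2.25. With CPM values the difference became 6.16 (granule cell), 7.82 (oligodendrocyte), 6.34 (molecular layer interneuron), 8.32 (microglia), 7.51 (endothelial cell or pericyte), 4.29 (blood), 9.50 (unipolar brush cell), 9.90 (oligodendrocyte precursor), 10.61 (choroid plexus or ependyma), 10.57 (forebrain neuron) and 10.68 (outside the brain). With a pseudocount of 0.1 it was 6.13 (molecular layer interneuron), 8.43 (Golgi or glycinergic neuron), 9.67 (unipolar brush cell), 10.9995 (oligodendrocyte precursor), 11.92 (choroid plexus or ependyma), 11.77 (forebrain neuron) and 12.13 (outside the brain), where genes near 0 set the values by construction. With means it was 6.06 (granule cell), 6.26 (oligodendrocyte) and 6.58 (molecular layer interneuron).

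By expected counts, which weight length by construction, the shares were 44.7% (Gria2), 61.0% (Grik1), 57.6% (Grin1), 82.7% (Kcna1), 54.7% (Scn1a), 78.1% (Scn2b), 36.1% (Cacna1a), 93.4% (Kcnn2), 99.4% (Itpr1), 81.2% (Plcb4), 91.7% (Homer3), 81.2% (Slc1a3), 47.7% (Syt4).

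For the ratio of the pools, the adjustment for length and expression gave -0.22 (Purkinje cell), -0.086 (Bergmann glia or astrocyte), 0.066 (molecular layer interneuron), 0.46 (microglia), -0.21 (metabotropic glutamate and calcium store signalling), -0.28 (intrinsic excitability), -0.23 (GABA synthesis, packaging and uptake), -0.11 (transcription factors of Purkinje cells), -0.18 (inherited ataxia genes), -0.28 (zebrin-negative band) and 0.030 (neurofilament and axon). With it the interneuron and neurofilament lists changed sign, as did calcium binding (-0.014). Counts scaled with TMM gave -0.096 (Bergmann glia or astrocyte), 0.54 (microglia), 0.38 (endothelial cell or pericyte), -0.30 (metabotropic glutamate and calcium store signalling), -0.12 (transcription factors of Purkinje cells) and 0.15 (nuclear oxidative phosphorylation), and with DESeq2 size factors -0.099 (Bergmann glia or astrocyte), 0.53 (microglia), 0.38 (endothelial cell or pericyte), -0.30 (metabotropic glutamate and calcium store signalling), -0.13 (transcription factors of Purkinje cells) and 0.15 (nuclear oxidative phosphorylation). A pseudocount of 0.1 gave 0.53 for microglia. With the spike-ins as the scale, which raises the ratio of every gene by the same amount, the values that changed sign were 0.38 (Purkinje cell), 0.46 (Bergmann glia or astrocyte), 0.48 (oligodendrocyte), 0.61 (molecular layer interneuron), 0.33 (metabotropic glutamate and calcium store signalling), 0.18 (intrinsic excitability), 0.25 (GABA synthesis, packaging and uptake), 0.37 (transcription factors of Purkinje cells), 0.42 (inherited ataxia genes), 0.18 (zebrin-negative band), 0.62 (neurofilament and axon) and 0.44 (sex check), and those that kept it were 1.07 (granule cell), 0.81 (Golgi or glycinergic neuron), 1.00 (microglia), 0.79 (endothelial cell or pericyte), 2.503 (blood), 0.77 (calcium binding), 1.28 (zebrin-positive band), 0.75 (nuclear oxidative phosphorylation), 0.82 (immediate early) and 0.72 (heat shock and stress). Spike-in amounts can differ by pipetting, so this scale does not by itself give the RNA per cell. At a mean TPM of 1 to 10, counting error alone would give the log2 ratio an SD of 0.22 against the observed 0.53, and at 10 to 100 an SD of 0.077 against 0.35, so depth was not the main part of that spread, as far as reads can be taken as independent.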

Other observations

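The gene groups in the next paragraph, and the tests of glial RNA, the spike-ins, the Purkinje cell list after adjustment, the other cell type lists, the vessel wall and each zebrin list alone, were chosen only after the results were seen, as was the length and expression adjustment itself. The tests of length on the difference of the zebrin lists, of GC content and of further zebrin genes were written before their adjusted values were computed. The test of length on the haemoglobin genes was also written then, but it and that of the vessel wall were dropped after the adjusted medians of the blood and endothelial lists had been seen. Both were later taken up again with the same bounds, and both count as chosen after.

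Metallothioneins, which bind zinc and copper, were abundant in both pools, with Mt1 at 4894 ± 116 TPM, Mt2 at 1315 ± 87.3 and Mt3 at 587 ± 73.6 (mean ± SD, n = 2). The 10 genes of glycolysis and energy supply looked at ranged widely and were not tested as a group: creatine kinase Ckb had 4756 ± 754 TPM, Ldhb 2391 ± 97.9, Gapdh 1720.5 ± 380.4, Aldoa 1101 ± 12.9, Eno1 603 ± 9.81, Pkm 481 ± 28.2, Pgk1 260 ± 12.4, Ckmt1 193 ± 0.948, Ldha 152 ± 8.46 and Eno2 122 ± 11.2. The neuropeptide genes Cck (1258 ± 187 TPM), Npy (310 ± 57.6) and Penk (93.0 ± 23.6) were detected, while Tac1 had 0.450 and 4.54 TPM in pools 1 and 2, Vip lay below a TPM of 1, and Cartpt and Pdyn had no counts. Among markers of monoamine and acetylcholine neurons, the monoamine transporter Slc18a2 had 3.05 and 3.72 TPM (224 and 347 counts), Tph2 0.700 and 0.610 (35 and 39 counts) and Ddc, the next enzyme after Th in dopamine synthesis, 0.480 and 0.700 (8 and 21 counts). Slc6a4 had 4 counts in pool 1 alone and Slc6a3 2 in pool 2 alone, and Dbh, Slc6a2 and Chat had none. Among genes picked because they were higher in pool 2 were Th (1.63 and 77.4 TPM), Sst (1.01 and 13.3), Prkcd (9.83 and 38.6), Kctd12 (40.5 and 96.3), Hspb1 (10.9 and 23.3) and Car7 (108 and 200). Sst had the highest mean TPM in the Golgi or glycinergic neuron list and Prkcd in the molecular layer interneuron list. Neither led its list in pool 1.

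Zebrin-positive genes were higher and zebrin-negative genes lower in pool 2, relative to the total. With the spike-ins as the scale the median of the zebrin-negative list was 0.18, while its member Plcb4 stayed lower. A length trend alone is argued against for the zebrin-positive list, whose adjusted median was 0.74 (percentile 99.98), but not for the zebrin-negative list, whose median went from -0.53 to -0.28 (percentile 3.97), so the adjusted difference of 1.02 between the lists, above all 10000 random pairs, rests mainly on the former. Glial RNA as the source of the Aldoc change is argued against as well, because the adjusted median of the Bergmann glia and astrocyte list was -0.086 (SD of members 0.31) and that of Aldoc 1.26. A hypothesis is that the pools may hold cells from different zebrin bands, but the test on genes not looked at before did not bear it out: Gabbr2 and Ncs1 less Map1a differed by -0.011, at percentile 50.1 of random lists. With 3 genes and the central 95% of the random lists reaching up to 0.72, this leaves the hypothesis open and without support from that test.

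Long transcripts were lower in pool 2 relative to short ones, with a Spearman's rho of ratio and length of -0.51 across genes. GC content is argued against as the whole cause, since within 5 bins of GC content over 6425 genes the rho closest to 0 was -0.310. The ratio of 42 spike-ins also fell with their length (rho = -0.418, two-sided permutation p = 0.00662), which is consistent with a step of library preparation that acts on length, since spike-ins do not come from the cells. The labels give no library date or batch, the preparation protocol is linked for pool 2 alone, and the spike-ins reach only 1994 nt, so the step and longer transcripts stay open.

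Most Purkinje cell genes were lower relative to the total and granule cell, microglial and haemoglobin genes higher in pool 2. With the spike-ins as the scale the Purkinje cell, granule cell, microglial and blood list medians were all positive (0.38 for the first). The length trend does not account for either side, as the adjusted Purkinje cell median was -0.22 (percentile 0.09) and that of the 4 haemoglobin genes was 1.73, above all random lists. If a lower share of Purkinje cell RNA were the only change, all lists free of that RNA would rise alike. The adjusted medians of 8 other lists over 70 genes had an SD of 0.605, against 0.177 with members shuffled (one-sided permutation p = 0.0004). Without the blood list the SD was 0.264 against 0.157 (one-sided permutation p = 0.0147). Genes of a list are not independent, so these p-values are too small. The test was also chosen after the medians of these lists had been seen to differ, so it restates that difference. A lower share can also occur together with uneven carry-over, so the test cannot decide on it and a lower share stays open. Endothelial and pericyte genes had an adjusted median of 0.16 (SD of members 0.16), and an unadjusted one of 0.38 with TMM-scaled counts. A rise of vessel wall as large as that of the haemoglobin genes is therefore argued against. Vessel wall and blood need not rise in the same proportion, so a smaller rise of vessel wall stays open. An earlier comparison of the granule and oligodendrocyte lists (0.71) took extremes after the medians were seen and is not used as a test, and uneven carry-over of blood and of neighbouring cells stays open.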
